A study of Homo sapiens with 45 samples.

How the data were processed

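The values are TPM for 61469 genes and 45 libraries, computed by the submitters and used as deposited. Per the submitters' processing notes, reads were trimmed with Trimmomatic, aligned to GRCh38 with STAR and counted with featureCounts, and differential expression was run with DESeq2. Tool versions, the gene annotation release and the strand setting of the counting are not given in the sources used here. Per the labels' protocols, RNA was extracted with RNeasy kits and poly(A) libraries were sequenced on a NovaSeq X. No sequence reads were processed here, and 6 lines of the file with broken values were left out.

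Read numbers were reconstructed from the TPM values. For each gene a length was sought, from GENCODE 29 (21603 genes) or from the values themselves (21246 genes), at which all libraries gave whole reads within 0.02 reads. This succeeded for 42849 of 45564 genes with any value above 0 (94.0%). Libraries held 13.3 to 26.4 M reads. Mitochondrial transcripts took 4.93 to 24.3% of TPM. In the compound and vehicle groups they took 11.5 to 19.8% in the 7 libraries numbered 1 and 4.93 to 9.63% in those numbered 2 and 3, so counts without the libraries numbered 1 stand beside each compound.

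Groups, comparisons, gene lists, tests, thresholds and most alternatives were fixed before the data were examined. The design assumed counts, with limma for a file without them. The file held TPM, so limma (trend, robust) was run on log2(TPM + 1). Libraries were scaled by a trimmed mean of log ratios, and genes with at least 10 reconstructed reads in at least 3 libraries of a comparison were tested. Joint fits, with a shared variance per gene, held the 24 knockdown-arm, the 21 compound and vehicle, or all 33 MDA-MB-231 libraries. Tests were 2-sided, Benjamini-Hochberg adjusted over a comparison's genes, with a threshold of adjusted p under 0.05. A self-test of all steps gave over 5% false calls in several comparisons.

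The self-test changed 200 genes in counts simulated at library depth with a dispersion of 0.03. In MDA-MB-231 POLE knockdown 19.4% of 1.5-fold, 67.2% of 2-fold and 98.5% of 4-fold changes were called, and in MCF7 11.9, 71.6 and 100%. Aphidicolin gave 23.9, 79.1 and 100%, and the MDA-MB-231 minus MCF7 difference 5.17, 29.3 and 98.4%. False calls were 9.56% of calls for POLE in MDA-MB-231, 4.65 in Hs578T, 14.7 in MCF7, 4.96 for POLD1, 9.89 for MDA-MB-231 minus MCF7, 7.53 for aphidicolin, 6.34 for cisplatin and 3.47% for paclitaxel. These shares apply to that dispersion, not to the variation across labels in Hs578T and POLD1.

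Gene lists were tested with camera (limma) at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, for lists with at least 5 measured members. Of 239 list tests in single comparisons 95 were called, and 3 held with an estimated correlation between genes: interferon-stimulated genes in MDA-MB-231, NF-kB targets in Hs578T and immediate-early genes with paclitaxel. Of 24 differences between lines or arms 18 were called and 6 held. The fry test, which asks if members move one way without comparison with other genes, called 71 and 10. Where a list's median, mean and test differed in sign, the list had no call. Tests of related lists are not independent.

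The 25 lists were NF-kB targets, the senescence-associated secretome (growth factors and proteases), interferon-stimulated genes, antigen presentation, cytosolic nucleic acid sensing, p53 targets, DNA replication, E2F and G1/S genes, G2/M and mitosis genes, Fanconi and homologous recombination genes, canonical histones, integrated stress response (ATF4) targets, unfolded protein response chaperones, AP-1 and immediate-early genes, apoptosis regulators, NRF2 targets, cholesterol synthesis, ribosomal proteins, ribosome biogenesis, tubulins, metallothioneins, oestrogen receptor targets, luminal markers, mesenchymal markers and leukocyte markers. Leukocyte markers were tested only in Hs578T, with 1 higher and 0 lower of 6 (1 and 1 adjusted over the list alone, limma camera adjusted p = 0.960).

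Named genes followed a rule. POLE and POLD1 and 10 fixed genes (NFKBIA, TNFAIP3, IL6, CXCL8, CXCL1, IFIT1, ISG15, CDKN1A, CCNE2 and CCNB1) were always eligible. To these came the 8 largest rises and falls of a comparison (5 in a difference) among genes past the test with at least 50 mean reads in the higher group and no overlap of libraries, and the 3 members with the largest change of each called list. Some genes that the rule names are not reported here. ESR1, IL11 in the POLD1 arm and cisplatin's long genes outside the rule were added after their values were seen.

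Whether replicate numbers pair libraries was asked from correlations of residuals across genes between libraries of equal number. All such correlations were above 0.1 for hydroxyurea (0.184 to 0.433), paclitaxel (0.139 to 0.309) and the vehicles (0.175 to 0.235), where a replicate block gave 3678, 228 and 1 genes against 3384, 154 and 0. This was not so for POLE in MDA-MB-231 (−0.030 to 0.288), Hs578T (−0.234 to 0.162) or MCF7 (−0.058 to 0.015), for POLD1 (−0.440 to 0.560), or for aphidicolin, cisplatin and cycloheximide.

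Pearson correlations between replicates of log2 values across genes went down to 0.922 in cisplatin, 0.959 in aphidicolin and 0.968 in Hs578T knockdown. Alternatives were other scalings, pseudocount 0.1, no or a stricter filter, single comparisons, a replicate block, single vehicles, a 2-fold threshold and each library left out. Chosen after seeing the data were limma-voom on reconstructed reads, array quality weights, leaving out cisplatin 3 with aphidicolin 2, and leaving out the libraries numbered 1. Software was Python 3.11.15 (numpy 2.4.6, matplotlib 3.10.9) and R 4.3.3 (limma 3.58.1).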

Results

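Poly(A) RNA was measured in 45 libraries of 3 established human breast cancer cell lines, in 15 groups of 3 libraries. MDA-MB-231 and Hs578T are triple-negative lines with mesenchymal traits, and MCF7 is a luminal line that carries the oestrogen receptor. ESR1, the gene of that receptor, stood at 72.6 ± 11.4 TPM (SD, n = 3) in MCF7 controls and below 1 TPM in both other lines. In each line POLE, the catalytic subunit of the leading-strand DNA polymerase epsilon, was targeted by an shRNA. Control groups also carried an shRNA-resistant POLE cDNA, and knockdown groups an empty vector. MDA-MB-231 had the same pair of groups for POLD1, the catalytic subunit of DNA polymerase delta, an arm given by the library titles and absent from the series text. Knockdown lasted 6 days by the series text and 5 days by the protocol text.

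A further 21 libraries of MDA-MB-231 came from cells treated for 24 h. The compounds were aphidicolin at 2 µg/mL, which inhibits replicative DNA polymerases, and hydroxyurea at 2 mM, which inhibits ribonucleotide reductase. Cisplatin at 12 µM forms DNA crosslinks, cycloheximide at 2 µM blocks translation, and paclitaxel at 4 nM stabilises microtubules. The vehicles were DMSO and NaCl, and the labels do not say which vehicle belongs to which compound, so each compound was compared with the mean of both. The median library had 19.6 M reads. The labels do not say whether libraries of a group came from separate cultures, so the replicates may be technical.

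It was asked which genes changed with POLE or POLD1 knockdown and with each compound. The POLE change was compared between lines, with POLD1 and with each compound. Folds are of TPM + 1 after scaling, so near 1 TPM they lie below ratios of the printed means. All coordinates are GRCh38 with the gene models of GENCODE 29. POLE lies on chromosome 12 at 132623753 to 132687365 (minus strand) and POLD1 on chromosome 19 at 50384204 to 50418016 (plus strand).

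POLE or POLD1 level was lower in every knockdown library than in all controls of its comparison. In MDA-MB-231 it was 18.0, 20.9 and 21.7 TPM in knockdown libraries and 880, 678 and 329 TPM in controls, 29.2-fold lower (limma adjusted p = 9.75e-12). Hs578T had 14.5, 10.5 and 12.1 TPM against 787, 632 and 503 TPM, 49.8-fold lower (limma adjusted p = 1.10e-12). MCF7 had 20.3, 21.8 and 20.4 TPM against 177, 154 and 193 TPM, 7.94-fold lower (limma adjusted p = 8.80e-08). POLD1 in its own arm was 23.7, 26.8 and 24.0 TPM against 935, 965 and 597 TPM, 30.8-fold lower (limma adjusted p = 6.32e-14).

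Control values include reads of the resistant cDNA, so these folds overstate the loss of the cells' own transcript. MDA-MB-231 cells without any construct had 51.9 TPM (DMSO) and 50 TPM (NaCl) of POLE, and 70.9 and 70.4 TPM of POLD1. Changes in that line thus compared knockdown with raised target levels. No construct-free Hs578T or MCF7 cells were measured. In the POLD1 arm POLE stood at 43.1 (controls) and 45.5 TPM (knockdown).

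**Figure D1:**
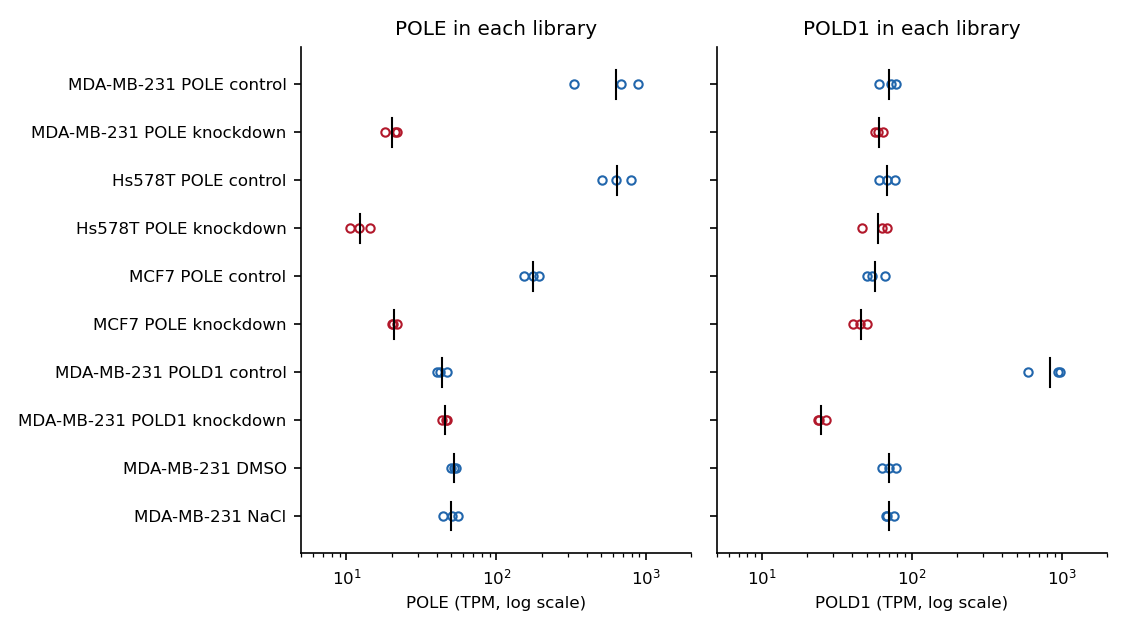
POLE and POLD1 level (TPM, log axis) in each library of the control, knockdown and vehicle groups. Open circles are libraries, red for knockdown and blue for the others, and the black line is the group mean. POLE means in MDA-MB-231 were 629 TPM in controls, 20.2 TPM in knockdown and 51.9 TPM in DMSO.

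After POLE knockdown in MDA-MB-231, the largest rises included cytokine genes. CSF3, which encodes the growth factor of neutrophils (chromosome 17 at 40015361 to 40017813), stood at 117 ± 36.8 TPM against 2.87 ± 3.91 TPM in controls, a 39.5-fold rise (limma adjusted p = 0.00147). CSF2, the growth factor of macrophages and granulocytes, rose 13.3-fold, from 37.3 ± 31.6 to 436 ± 30 TPM (limma adjusted p = 5.70e-04). The neutrophil chemokines CXCL1 (11.7-fold, from 31.5 ± 19.9 to 359 ± 29.2 TPM) and CXCL8 (7.51-fold, from 45.0 ± 15.7 to 351 ± 19.8 TPM) rose, as did IL1B (11.6-fold), IL1A (9.72-fold), CCL20 (9.32-fold) and IL6 (8.51-fold, from 19.3 ± 16.1 to 149 ± 33.1 TPM). The log2 fold change of IL6 was 3.66 without control 1 and 2.65 without control 3. The cell-cycle inhibitor CDKN1A rose 3.03-fold, from 138 ± 10.6 to 444 ± 23.5 TPM (limma adjusted p = 3.39e-05). ESM1, an endothelial proteoglycan gene, fell from 97.4 ± 83.1 to 0.542 ± 0.414 TPM (log2 fold change −5.62, limma adjusted p = 5.31e-04), and the chemokine receptor CXCR4 fell (log2 fold change −2.60). Of 59 named genes that passed, 57 had no overlap of libraries, in part by the naming rule.

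Interferon-stimulated genes rose in the same comparison. The type III interferon IFNL1 rose 6.31-fold (limma adjusted p = 5.12e-04), and the chemokines of interferon-treated cells CXCL11 (6.92-fold, from 2.34 ± 0.382 to 24.0 ± 6.62 TPM) and CXCL10 (log2 fold change 2.10) rose. ISG15, a ubiquitin-like protein gene on chromosome 1 at 1001138 to 1014540, rose 2.51-fold, from 343 ± 64.5 to 921 ± 216 TPM (limma adjusted p = 1.70e-05). Of 40 measured interferon-stimulated genes, 28 rose and 0 fell (35 and 0 adjusted over the list alone), with a median log2 fold change of 0.88 (camera adjusted p = 2.79e-23), and this call held with adjusted p = 0.0283 with estimated correlation. IFIT1 rose (log2 fold change 0.93, limma adjusted p = 0.0256), a call lost without control 2 (0.0916) and without 4 of the other 5 libraries. Of 22 antigen presentation genes, 7 rose, among them HLA-B and HLA-F (0.78 and 0.96), and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 3.65e-06, adjusted p = 0.365 with estimated correlation). Among 17 nucleic acid sensing genes 6 rose, including DHX58 and IKBKE (both 0.86), and 0 fell (9 and 1 adjusted over the list alone, camera adjusted p = 4.74e-04, adjusted p = 0.140 with estimated correlation).

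Targets of the transcription factor NF-kB rose as a group. Of 40 measured NF-kB targets 35 rose and 0 fell (38 and 0 adjusted over the list alone), with a median log2 fold change of 1.62 (camera adjusted p = 7.65e-28, adjusted p = 0.245 with estimated correlation). TNFAIP3, an inhibitor of that pathway, rose (log2 fold change 1.02, limma adjusted p = 0.00314). NFKBIA also rose by 1.02 (limma adjusted p = 0.0106), with adjusted p = 0.0552 without control 2. The list of secreted growth factors and proteases of the senescence-associated secretome, without a member in common with the NF-kB list, had 8 genes higher and 1 lower of 23 (9 and 1 adjusted over the list alone, camera adjusted p = 4.34e-05, adjusted p = 0.299 with estimated correlation).

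Among 34 targets of p53, 10 rose, including TP53INP1 (1.16) and BBC3 (1.00), and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 5.15e-04, adjusted p = 0.140 with estimated correlation). Of 21 apoptosis genes 7 rose, including BIK (1.70) and TNFSF10 (1.33), and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 0.0125, adjusted p = 0.255 with estimated correlation). Of 30 AP-1 and immediate-early genes 7 rose, including JUNB (1.10) and RHOB (0.98), and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.0145, adjusted p = 0.579 with estimated correlation), a call lost without control 2 (adjusted p = 0.0702) or knockdown 1 (0.0951). In this poly(A) RNA, histone genes rose in 4 of 13 members, such as H2AC11 (1.45), and fell in 0 (5 and 0 adjusted over the list alone, camera adjusted p = 0.0145, adjusted p = 0.384 with estimated correlation), a call lost without knockdown 1 (0.127).

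In proliferation and ribosome lists a minority fell, with no call at estimated correlation. The helicase genes MCM6 (from 172 ± 21.2 to 96.3 ± 16.9 TPM, log2 fold change −0.92, limma adjusted p = 0.00114) and MCM5 (−0.73) were among 8 lower and 0 higher of 56 DNA replication genes (8 and 0 adjusted over the list alone, median −0.18, camera adjusted p = 4.34e-05, adjusted p = 0.555 with estimated correlation). PLK1 (−1.09) and CDC20 (−0.90) were among 4 lower and 0 higher of 40 G2/M genes (4 and 0 adjusted over the list alone, median −0.44, camera adjusted p = 2.27e-09, adjusted p = 0.487 with estimated correlation). UNG (−0.56) was 1 of 3 lower, with 0 higher, among 28 E2F targets (3 and 0 adjusted over the list alone, camera adjusted p = 0.00504, adjusted p = 0.579 with estimated correlation), a call lost without knockdown 1 (0.176). RPS2 (−0.42) was 1 of 8 lower, with 0 higher, among 38 ribosomal protein genes (16 and 0 adjusted over the list alone, camera adjusted p = 2.27e-09, adjusted p = 0.451 with estimated correlation). FBL (−0.61, from 803 to 558 TPM) was 1 of 7 lower, with 0 higher, among 34 ribosome biogenesis genes (10 and 0 adjusted over the list alone, camera adjusted p = 5.59e-08, adjusted p = 0.365 with estimated correlation). CCNB1 changed by −0.64 (limma adjusted p = 0.110) and CCNE2 by 0.14 (0.673).

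In total 1342 genes rose and 822 fell of 16141 tested by limma, 308 and 40 of them by at least 2-fold (1694 and 462 with no further scaling). The count was 1345 without control 3, 1194 without knockdown 1 and 1442 without knockdown 3. Lists without a call were Fanconi anaemia and homologous recombination (0 higher and 2 lower of 36, 0 and 0 adjusted over the list alone, limma camera adjusted p = 0.0847), ATF4 targets (1 and 4 of 29, alone 1 and 5, adjusted p = 0.0574), unfolded protein response (2 and 1 of 20, alone 3 and 1, adjusted p = 0.215) and NRF2 targets (0 and 2 of 24, alone 0 and 2, adjusted p = 0.107). The same held for cholesterol synthesis (0 and 2 of 25, 0 and 2 adjusted over the list alone, limma camera adjusted p = 0.196), tubulins (1 and 0 of 12, alone 1 and 0, adjusted p = 0.411), metallothioneins (0 and 0 of 5, alone 0 and 0, adjusted p = 0.543), oestrogen receptor targets (1 and 1 of 14, alone 2 and 1, adjusted p = 0.666), luminal markers (3 and 1 of 13, alone 3 and 1, adjusted p = 0.214) and mesenchymal markers (0 and 1 of 21, alone 0 and 1, adjusted p = 0.739). Fanconi anaemia genes were called without control 1 (0.00352) or knockdown 3 (0.0104), ATF4 targets without control 2 (0.0342), control 3 (0.0488) or knockdown 1 (0.00654), unfolded protein response without control 3 (0.0488) or knockdown 1 (0.0385), and cholesterol synthesis without knockdown 2 (0.0467).

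Hs578T raised CCL20 and CSF2 after POLE knockdown while its interferon-stimulated genes had a median near 0. The chemokine CCL20 rose from 1.64 ± 0.808 to 20.4 ± 9.07 TPM (log2 fold change 2.94, limma adjusted p = 0.00351) and CSF2 from 6.65 ± 3.34 to 55.2 ± 4.64 TPM (2.93, limma adjusted p = 0.01). CDKN1A rose from 51.8 ± 14.3 to 168 ± 56.2 TPM (1.60, limma adjusted p = 1.32e-04). H1-0, a linker histone of resting cells, fell from 995 ± 62.5 to 447 ± 33.1 TPM (−1.22, limma adjusted p = 1.27e-04), and LAMP3 fell (−1.39). CXCL8 had 603 ± 139 TPM in controls and 1698 ± 52.0 TPM in knockdown libraries (limma adjusted p = 0.232), IL6 a log2 fold change of 1.69 (limma adjusted p = 0.0798), ISG15 0.13 (0.682) and IFIT1 −0.37 (0.479). Of 29 named genes that passed, 28 had no overlap.

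Of 37 measured NF-kB targets in Hs578T, 13 rose, including TNFAIP3 (0.93), and 0 fell (25 and 0 adjusted over the list alone), with a median log2 fold change of 0.96 (camera adjusted p = 1.71e-17), a call that held with adjusted p = 0.0139 with estimated correlation. Interferon-stimulated genes had 0 higher and 2 lower of 39 (1 and 2 adjusted over the list alone, median 0.06, limma camera adjusted p = 0.960). The secretome list had 3 higher and 0 lower of 26 (7 and 0 adjusted over the list alone, camera adjusted p = 1.13e-04, adjusted p = 0.606 with estimated correlation), lost without knockdown 1 (0.108). BTG2 (0.95) was 1 of 6 higher, with 1 lower, among 34 p53 targets (8 and 1 adjusted over the list alone, camera adjusted p = 0.00127, adjusted p = 0.297 with estimated correlation). Histone genes rose in 3 of 14 members and fell in 0 (7 and 0 adjusted over the list alone, camera adjusted p = 7.95e-05, adjusted p = 0.606 with estimated correlation), lost without knockdown 1 (0.108).

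G2/M genes in Hs578T had 0 higher and 0 lower of 40 (0 and 0 adjusted over the list alone) and a median log2 fold change of −0.16 (camera adjusted p = 0.0201, adjusted p = 0.965 with estimated correlation), turned in direction without control 3 (0.0554) and lost without knockdown 1 (0.470). Immediate-early genes had 0 and 0 of 30 (2 and 0 adjusted over the list alone, camera adjusted p = 0.0181, adjusted p = 0.903 with estimated correlation), lost without control 3 (0.564) or knockdown 1 (0.591). Ribosomal protein genes had 0 higher and 2 lower of 38 (0 and 9 adjusted over the list alone, median −0.22, camera adjusted p = 4.40e-09, adjusted p = 0.606 with estimated correlation). Ribosome biogenesis genes had 0 and 1 of 34 (0 and 2 adjusted over the list alone, median −0.22, camera adjusted p = 3.05e-05, adjusted p = 0.525 with estimated correlation). DNA replication genes had 1 higher and 0 lower of 56 (1 and 0 adjusted over the list alone, limma camera adjusted p = 0.960). In total 488 genes rose and 235 fell of 17419 by limma, 149 and 21 by at least 2-fold (630 and 116 with no further scaling), with 81 genes when fitted alone (only the libraries of the comparison), 402 without control 1, 365 without control 2 and 399 without knockdown 2. Across the labels, knockdown 1 with controls 1 and 2 (mitochondrial share 16.5, 12.5 and 17.3%) against the other libraries (8.02 to 9.04%) gave 699 genes.

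In MCF7 the genes that rose after POLE knockdown included p53 targets. CDKN1A went from 299 ± 42.4 to 527 ± 25.7 TPM (log2 fold change 0.84, limma adjusted p = 0.0341, with 0.197 without control 3), TP53INP1 rose by 0.93 (limma adjusted p = 0.0408, with 0.181 without knockdown 1) and ZMAT3 by 0.82 (limma adjusted p = 0.0235, with 0.137 without knockdown 1). These 3 calls were lost with 6, 6 and 5 of the 6 libraries left out in turn. The stress keratin KRT16 rose from 3.00 ± 0.511 to 10.2 ± 1.97 TPM (limma adjusted p = 0.00460). H1-0 fell (−0.87, limma adjusted p = 0.00671, with 0.0544 without control 3). ISG15 had a log2 fold change of 0.21 (limma adjusted p = 0.641). CXCL8 stood at 0.115 TPM in controls and 0.572 TPM in knockdown libraries, and IL6 at 0.0740 and 0.102 TPM. All 23 named genes that passed had no overlap, in part by the naming rule.

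Of 34 measured p53 targets in MCF7, 10 rose and 0 fell (27 and 0 adjusted over the list alone), with a median log2 fold change of 0.44 (camera adjusted p = 1.18e-23, adjusted p = 0.147 with estimated correlation). NF-kB targets had 2 higher and 0 lower of 22 (2 and 0 adjusted over the list alone, median 0.15, camera adjusted p = 0.0305, adjusted p = 0.302 with estimated correlation), lost without control 3 (0.0822), knockdown 1 (0.0505) or knockdown 2 (0.0953). Interferon-stimulated genes had 2 and 1 of 25 (4 and 1 adjusted over the list alone, limma camera adjusted p = 0.0693), called without control 1 (0.0447), control 2 (0.0497) or knockdown 3 (0.00693). The secretome list had 1 and 0 of 20 (3 and 0 adjusted over the list alone, camera adjusted p = 0.00139, adjusted p = 0.302 with estimated correlation). Antigen presentation had 0 and 0 of 16 (1 and 0 adjusted over the list alone, median 0.20, camera adjusted p = 0.00125, adjusted p = 0.302 with estimated correlation). Immediate-early genes had 2 and 0 of 29 (4 and 0 adjusted over the list alone, camera adjusted p = 0.00125, adjusted p = 0.302 with estimated correlation).

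G2/M genes in MCF7 had 0 and 0 of 40 (0 and 0 adjusted over the list alone, median −0.31, camera adjusted p = 3.90e-10, adjusted p = 0.302 with estimated correlation). DNA replication genes had 0 and 0 of 56 (0 and 0 adjusted over the list alone, median −0.08, camera adjusted p = 0.00125, adjusted p = 0.302 with estimated correlation). Oestrogen receptor targets (0 and 0 of 21, limma camera adjusted p = 0.292) and luminal markers (0 and 0 of 18, adjusted p = 0.923) had no call. In total 122 genes rose and 30 fell of 16067 by limma, 25 and 6 by at least 2-fold. The count was 69 without control 2, 23 without control 3, 23 without knockdown 1, 43 without knockdown 2 and 32 without knockdown 3.

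The change of interferon-stimulated genes after POLE knockdown was larger in MDA-MB-231 than in MCF7. ICAM1, an adhesion molecule driven by NF-kB, changed by 2.17 log2 units more (limma adjusted p = 0.00907), the interferon-stimulated ligase HERC5 by 1.09 (0.00142) and ISG15 by 1.12 (0.0101). NF-kB targets had 8 genes with a larger and 0 with a smaller change of 22 (14 and 0 adjusted over the list alone), a median difference of 1.04 (camera adjusted p = 8.10e-17, adjusted p = 0.0588 with estimated correlation). Interferon-stimulated genes had 4 and 0 of 25 (12 and 0 adjusted over the list alone), a median difference of 0.65 (camera adjusted p = 9.31e-15), which held with adjusted p = 0.0158 with estimated correlation. For p53 targets 0 changes were larger and 1 smaller of 32 (1 and 3 adjusted over the list alone), a median difference of −0.20 (camera adjusted p = 0.0138, adjusted p = 0.124 with estimated correlation). In total 94 genes had a larger and 61 a smaller log2 change in MDA-MB-231 of 13849 (125 and 22 with no further scaling, 473 genes when fitted alone). Leaving out MDA-MB-231 control 2 gave 97, control 3 gave 93, knockdown 1 gave 74 and knockdown 2 gave 80, and leaving out MCF7 control 3 gave 91, knockdown 1 gave 78, knockdown 2 gave 85 and knockdown 3 gave 70.

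MDA-MB-231 and Hs578T differed in interferon-stimulated genes. LAMP3, an interferon-induced lysosomal gene, changed by 2.92 log2 units more in MDA-MB-231 (limma adjusted p = 7.47e-05) and OAS2 by 1.69 (0.00121). Interferon-stimulated genes had 10 larger and 0 smaller changes of 38 (30 and 0 adjusted over the list alone), a median difference of 0.87 (camera adjusted p = 2.34e-29), which held with adjusted p = 4.41e-04 with estimated correlation. NF-kB targets had 2 and 0 of 34 (5 and 0 adjusted over the list alone), a median difference of 0.57 (camera adjusted p = 1.18e-08, adjusted p = 0.162 with estimated correlation). IL6 differed by 1.40 (limma adjusted p = 0.455) and CXCL8 by 1.46 (0.557). In total 62 changes were larger and 48 smaller of 14718 (20 genes when fitted alone). Leaving out MDA-MB-231 control 1 gave 177, control 2 gave 36, control 3 gave 52, knockdown 1 gave 45, knockdown 2 gave 54 and knockdown 3 gave 61, and leaving out Hs578T control 1 gave 53, control 2 gave 49, knockdown 1 gave 192 and knockdown 2 gave 70.

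Hs578T exceeded MCF7 in NF-kB targets by a median of 0.41 (camera adjusted p = 7.03e-06, held with adjusted p = 0.00731 with estimated correlation), although 0 of 21 members had a larger or smaller change by themselves (3 and 0 adjusted over the list alone). The p53 targets had 0 larger and 1 smaller of 32 (1 and 8 adjusted over the list alone), a median difference of −0.24 (camera adjusted p = 7.62e-04, held with adjusted p = 0.0485 with estimated correlation). LAMP3 changed by −1.96 (limma adjusted p = 0.00744) relative to MCF7. In total 23 changes were larger and 23 smaller of 14057 (27 and 6 with no further scaling, 32 and 21 with median-of-ratios scaling, 11 genes when fitted alone). Leaving out Hs578T control 1 gave 9, knockdown 1 gave 90, knockdown 2 gave 25 and knockdown 3 gave 26, and leaving out MCF7 control 1 gave 19, control 2 gave 19, control 3 gave 21, knockdown 1 gave 13, knockdown 2 gave 8 and knockdown 3 gave 13.

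Genes that rose in MDA-MB-231 overlapped those that rose in both other lines. With Hs578T 185 risen genes were shared against 32.9 from chance (adjusted Fisher p = 5.21e-95 across genes) and 85 fallen genes against 11.6 (4.23e-51), with a Pearson correlation of log2 fold changes of 0.46 across genes. With MCF7 35 risen genes were shared against 7.74 (1.35e-14) and 6 fallen genes against 1.12 (8.59e-04), with a correlation of 0.26 across genes. Genes are not independent replicates.

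**Figure D2:**
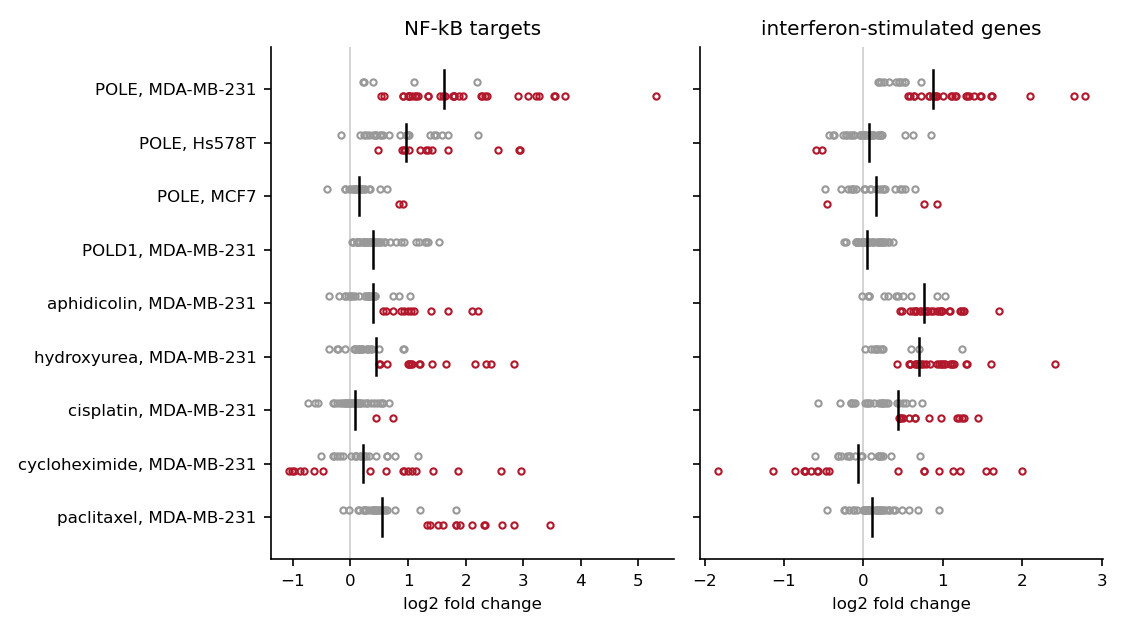
Log2 fold changes of measured NF-kB targets and interferon-stimulated genes in 9 comparisons. Red points have limma adjusted p < 0.05, grey points do not, and the black line is the median. NF-kB medians were 1.62 in MDA-MB-231, 0.96 in Hs578T and 0.15 in MCF7, and interferon-stimulated medians 0.88, 0.06 and 0.16.

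POLD1 knockdown in MDA-MB-231 left POLD1 as the only gene past the test by limma (0 higher and 1 lower of 16584). At unadjusted p below 0.05 there were 529 genes, limma-voom called 1 gene and a fit with a replicate block 1 gene, while array quality weights, which discount libraries that lie apart from their group, gave 7121. CXCL8 had 148 ± 145 TPM in controls and 330 ± 245 TPM in knockdown libraries (log2 fold change 1.14, limma adjusted p = 0.999), IL6 a log2 fold change of 0.93, ISG15 0.20 and CDKN1A 0.11 (limma adjusted p = 0.999 for each). The count was 5 without knockdown 1, and 1857 without knockdown 1 and control 3, an alternative withdrawn because these were picked for lying across the labels.

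The 6 libraries of the POLD1 arm fell into sets that cut across the groups. Knockdown 2, knockdown 3 and control 3 had CXCL8 at 316 to 546 TPM and IL11 at 97.2 to 112 TPM, while knockdown 1, control 1 and control 2 had CXCL8 at 60.5 to 68.2 TPM and IL11 at 358 to 460 TPM. The first principal component of these libraries held 64.5% of the variance. The lists that camera called had 0 higher and 0 lower members each (0 and 0 adjusted over the list alone). NF-kB targets had a median log2 fold change of 0.39 (limma camera adjusted p = 9.92e-13), DNA replication genes 0.17 (1.19e-09), antigen presentation 0.21 (3.65e-05), E2F targets 0.19 (1.29e-06), Fanconi anaemia genes 0.13 (3.57e-04), immediate-early genes −0.10 (0.0208) and ribosome biogenesis 0.09 (0.00256). For the first 6 lists adjusted p = 0.736 with estimated correlation, and for ribosome biogenesis 0.886. The immediate-early call was lost without control 1 (0.209), control 2 (0.160), knockdown 2 (0.122) or knockdown 3 (0.398), and the ribosome biogenesis call without the same libraries (0.209, 0.446, 0.426 and 0.405). Histones (3.88e-05 and 2.82e-04), NRF2 targets (0.00118 and 0.00108) and ribosomal proteins (3.88e-05 and 2.88e-05) gained a call without control 3 or knockdown 1.

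**Figure D3:**
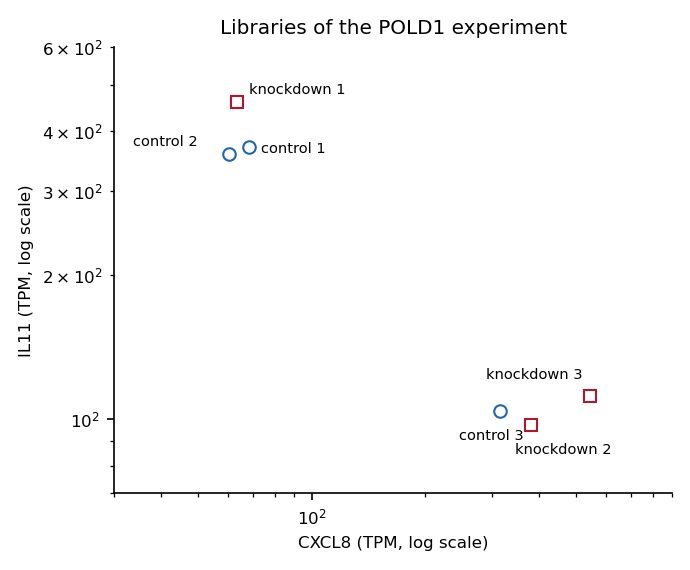
CXCL8 against IL11 level (TPM, log axes) in the 6 libraries of the POLD1 arm. Circles are controls and squares knockdown libraries. Control 3 lay with knockdown 2 and 3 (CXCL8 316 to 546 TPM), and knockdown 1 with controls 1 and 2 (60.5 to 68.2 TPM).

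The POLE change in MDA-MB-231 exceeded the POLD1 change for interferon-stimulated genes. TNFSF15 differed by 2.61 log2 units (limma adjusted p = 1.49e-04), ICAM1 by 2.04 (0.00978), CDKN1A by 1.49 (0.00660) and ISG15 by 1.13 (0.00695). The helicase gene MCM5 had a lower change in the POLE arm (−0.95, limma adjusted p = 0.0253), lost without POLD1 knockdown 2 (0.0878) and with 6 other libraries. Interferon-stimulated genes had 15 larger and 0 smaller changes of 38 (21 and 0 adjusted over the list alone), a median difference of 0.68 (camera adjusted p = 1.48e-17), held with adjusted p = 2.86e-04 with estimated correlation. NF-kB targets had 9 and 0 of 39 (19 and 0 adjusted over the list alone), a median of 1.13 (camera adjusted p = 2.38e-15, adjusted p = 0.166 with estimated correlation), and CXCL8 itself a difference of 1.77 (limma adjusted p = 0.286). In total 316 changes were larger and 156 smaller of 15565 (405 and 69 with no further scaling, which shifts the median of all genes by 0.12). The count was 240 when fitted alone and 3519 with the withdrawn alternative. It moved with single libraries of both arms: 312 without POLE control 2, 221 without POLE control 3, 179 without POLE knockdown 1, 252 without POLE knockdown 3, 157 without POLD1 control 1, 153 without POLD1 control 2, 1543 without POLD1 control 3, 1666 without POLD1 knockdown 1, 153 without POLD1 knockdown 2 and 170 without POLD1 knockdown 3.

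The vehicles NaCl and DMSO did not differ in any single gene (0 of 15050 by limma, 263 at unadjusted p below 0.05, limma-voom 0, 1 with a replicate block and 9 with array quality weights). Camera nevertheless called several lists with 0 members past the test: interferon-stimulated genes at a median of 0.20 (camera adjusted p = 1.94e-06, adjusted p = 0.159 with estimated correlation), ATF4 targets at −0.15 (6.38e-10, 0.285), histones at −0.28 (1.46e-04, 0.343) and mesenchymal markers at 0.14 (0.00281, 0.285). Immediate-early genes shifted by −0.14 (0.00760, 0.343), luminal markers by 0.16 (0.00760, 0.394), NF-kB targets by 0.07 (0.0177, 0.691), the secretome by 0.09 (0.0251, 0.488) and antigen presentation by 0.07 (0.0301, 0.682), the last number being adjusted p with estimated correlation. ATF4 targets had 0 and 2 members and luminal markers 1 and 0 adjusted over the list alone, and the others 0 and 0. Like the POLD1 calls, these count among the 95 list calls, and calls with such shifts elsewhere are weak evidence. Leaving out DMSO 3 ended the NF-kB (0.568), secretome (0.276) and antigen presentation (0.384) calls, and so did NaCl 1 (0.992, 0.524 and 0.649). DMSO 2 ended the antigen presentation (0.106), histone (0.105) and immediate-early (0.275) calls, and DMSO 1 (0.0752), NaCl 1 (0.308) and NaCl 3 (0.445) the luminal call.

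Aphidicolin raised CDKN1A, IL11 and CSF2 and lowered mitotic and ribosome biogenesis genes. CDKN1A (chromosome 6 at 36676460 to 36687339) rose 3.60-fold, to 635 ± 139 TPM from 171 ± 8.98 (DMSO) and 161 ± 12.7 TPM (NaCl), limma adjusted p = 5.64e-07. The fibrosis-linked cytokine IL11 rose 6.64-fold, to 91.4 ± 28.6 TPM from 12.8 ± 4.05 and 11.6 ± 2.25 TPM (limma adjusted p = 2.51e-06) and CSF2 rose by 1.70 log2 units (2.25e-04). H1-0 fell to 104 ± 2.89 TPM from 418 ± 47.4 and 431 ± 72.4 TPM (−2.07, limma adjusted p = 1.35e-09). CXCL8 had a log2 fold change of 1.04 (limma adjusted p = 0.102) and IL6 of 0.83 (0.110). Of 53 named genes that passed, 50 had no overlap, in part by the naming rule.

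Interferon-stimulated genes rose in 27 of 39 members with aphidicolin, such as CXCL11 (1.71) and OASL (1.26), and fell in 0 (31 and 0 adjusted over the list alone), with a median of 0.76 (camera adjusted p = 2.97e-14, adjusted p = 0.117 with estimated correlation). NF-kB targets had 12 and 0 of 38 (13 and 0 adjusted over the list alone, median 0.40, camera adjusted p = 1.15e-05, adjusted p = 0.353 with estimated correlation). G2/M genes had 1 higher and 20 lower of 40, including CDC20 (−1.27) and PLK1 (−1.15), with 1 and 24 adjusted over the list alone (camera adjusted p = 3.70e-10, adjusted p = 0.153 with estimated correlation). Ribosome biogenesis had 0 and 24 of 34, including RRS1 (−1.07), with 0 and 30 adjusted over the list alone (camera adjusted p = 8.13e-16, adjusted p = 0.154 with estimated correlation). Among p53 targets 8 rose, including FDXR (1.18), and 1 fell of 34 (9 and 1 adjusted over the list alone, camera adjusted p = 0.0140, adjusted p = 0.153 with estimated correlation).

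The secretome had 10 higher and 0 lower of 19 with aphidicolin (10 and 1 adjusted over the list alone, camera adjusted p = 4.66e-06, adjusted p = 0.153 with estimated correlation). Nucleic acid sensing, with STING1 at 1.09, had 5 and 0 of 17 (6 and 0 adjusted over the list alone, camera adjusted p = 0.0140, adjusted p = 0.311 with estimated correlation). Antigen presentation had 7 and 0 of 22 (9 and 0 adjusted over the list alone, camera adjusted p = 0.00190, adjusted p = 0.348 with estimated correlation). Histones, with H2AC6 at −1.21, had 0 and 5 of 14 (0 and 8 adjusted over the list alone, camera adjusted p = 5.22e-04, adjusted p = 0.172 with estimated correlation), and ATF4 targets, with ASNS at −0.98, 0 and 10 of 29 (0 and 11 adjusted over the list alone, camera adjusted p = 9.81e-04, adjusted p = 0.172 with estimated correlation). DNA replication had 11 higher and 4 lower of 56 (12 and 4 adjusted over the list alone, camera adjusted p = 0.0400, adjusted p = 0.514 with estimated correlation), lost without aphidicolin 2 (0.125), DMSO 3 (0.103) or NaCl 3 (0.0877). Apoptosis genes, with BIK at 1.99, had 5 and 1 of 21 (7 and 2 adjusted over the list alone, camera adjusted p = 0.0267, adjusted p = 0.153 with estimated correlation), lost without aphidicolin 1 (0.0645). Without aphidicolin 2, Fanconi anaemia genes (0.00394), NRF2 targets (0.0314) and ribosomal proteins (1.94e-05) gained a call. In total 1935 genes rose and 1116 fell of 15938 by limma, 501 and 73 by at least 2-fold (2109 and 446 with no further scaling). The count was 4579 without cisplatin 3 and aphidicolin 2 and 815 without the libraries numbered 1.

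Hydroxyurea raised CDKN1A, CSF2 and CXCL11 and lowered PLK1 and CDC20. CDKN1A rose 3.58-fold to 665 ± 49.5 TPM (limma adjusted p = 1.03e-07), CSF2 5.41-fold to 222 ± 51.8 TPM (5.67e-06), IL1A by 2.84 log2 units and IL11 by 2.42 (4.31e-06). CXCL11 rose to 18.8 ± 2.83 TPM (2.41, limma adjusted p = 3.13e-05). The mitotic kinase gene PLK1 fell (−1.36, limma adjusted p = 6.12e-07), and so did CDC20 (−1.56) and H1-0 (−1.77). Of 52 named genes that passed, 50 had no overlap, in part by the naming rule. In total 2141 genes rose and 1243 fell of 16075 by limma, 658 and 64 by at least 2-fold (2639 and 458 with no further scaling, which shifts the median of all genes by 0.16). The count was 2168 without hydroxyurea 1, 2110 without hydroxyurea 3, 3678 with a replicate block, 5289 when fitted alone, 5964 without cisplatin 3 and aphidicolin 2, and 1058 without the libraries numbered 1.

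Interferon-stimulated genes had 27 higher and 0 lower of 39 with hydroxyurea (30 and 0 adjusted over the list alone, median 0.70, camera adjusted p = 1.43e-12, adjusted p = 0.0536 with estimated correlation). NF-kB targets had 16 and 0 of 38 (18 and 0 adjusted over the list alone, median 0.44, camera adjusted p = 1.54e-06, adjusted p = 0.460 with estimated correlation). STING1 (1.41) was among 7 higher and 1 lower of 17 nucleic acid sensing genes (7 and 1 adjusted over the list alone, camera adjusted p = 0.0147, adjusted p = 0.237 with estimated correlation) and BTG2 (1.22) among 8 and 0 of 34 p53 targets (8 and 0 adjusted over the list alone, camera adjusted p = 0.00329, adjusted p = 0.220 with estimated correlation). G2/M genes had 2 and 17 of 40 (2 and 18 adjusted over the list alone, camera adjusted p = 8.08e-10, adjusted p = 0.259 with estimated correlation), and ribosome biogenesis genes, such as NOP56 (−0.82), 0 and 18 of 34 (0 and 24 adjusted over the list alone, camera adjusted p = 3.55e-12, adjusted p = 0.259 with estimated correlation).

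ATF4 targets, such as PSAT1 (−0.99), had 0 higher and 11 lower of 29 (0 and 11 adjusted over the list alone, camera adjusted p = 1.16e-04, adjusted p = 0.237 with estimated correlation), and NRF2 targets, such as NQO1 (−0.96), 2 and 6 of 24 (2 and 8 adjusted over the list alone, camera adjusted p = 0.00160, adjusted p = 0.516 with estimated correlation). The secretome had 10 and 1 of 21 (10 and 1 adjusted over the list alone, camera adjusted p = 1.27e-04, adjusted p = 0.259 with estimated correlation). Histones had 1 and 6 of 16 (1 and 6 adjusted over the list alone, camera adjusted p = 0.00464, adjusted p = 0.278 with estimated correlation). Ribosomal proteins had 0 and 2 of 38 (0 and 0 adjusted over the list alone, camera adjusted p = 1.67e-06, adjusted p = 0.516 with estimated correlation). Apoptosis genes had 6 and 1 of 21 (6 and 1 adjusted over the list alone, camera adjusted p = 0.0278, adjusted p = 0.259 with estimated correlation), the last lost without hydroxyurea 2 (0.0546).

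The largest falls with cisplatin included genes with long primary transcripts. CDH4, a cadherin gene spanning 688192 bases on chromosome 20 at 61252426 to 61940617, fell 7.48-fold, to 7.63 ± 2.40 TPM from 63.3 ± 10.4 (DMSO) and 70.1 ± 9.02 TPM (NaCl), limma adjusted p = 1.32e-09. SDK1 (span 967553, log2 fold change −2.23), GPC6 (span 1180560, −2.13) and TRAPPC9 (span 730855, −2.05, limma adjusted p = 1.29e-07) also fell. IL11 rose 4.21-fold to 51.6 ± 17.8 TPM (limma adjusted p = 8.15e-05). ISG15 rose to 815 ± 573 TPM (1.44, limma adjusted p = 0.0105). CDKN1A rose to 236 ± 6.71 TPM (0.61, limma adjusted p = 0.00905), a call lost without cisplatin 3 (0.0732). Of 40 named genes that passed, 36 had no overlap, in part by the naming rule.

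Across 13421 genes the log2 change with cisplatin had a Spearman correlation of −0.474 with gene span, and of −0.279 given transcript length, genes not being independent replicates. By library it was −0.291, −0.0563 and −0.503 in cisplatin 1, 2 and 3 (−0.245, −0.0158 and −0.274 given transcript length), and −0.30 to 0.19 in vehicle libraries. In the fifth with the longest spans 489 fell and 14 rose of 2684, and in the fifth with the shortest 49 fell and 125 rose of 2686. The 147 genes of at least 500 kb had a median log2 ratio to vehicles of −0.59, −0.40 and −0.86 in cisplatin 1, 2 and 3 (−0.09 to 0.09 in vehicle libraries), and of −0.54, −0.41 and −0.35 relative to genes of the same transcript length (−0.07 to 0.06 in vehicle libraries).

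**Figure D4:**
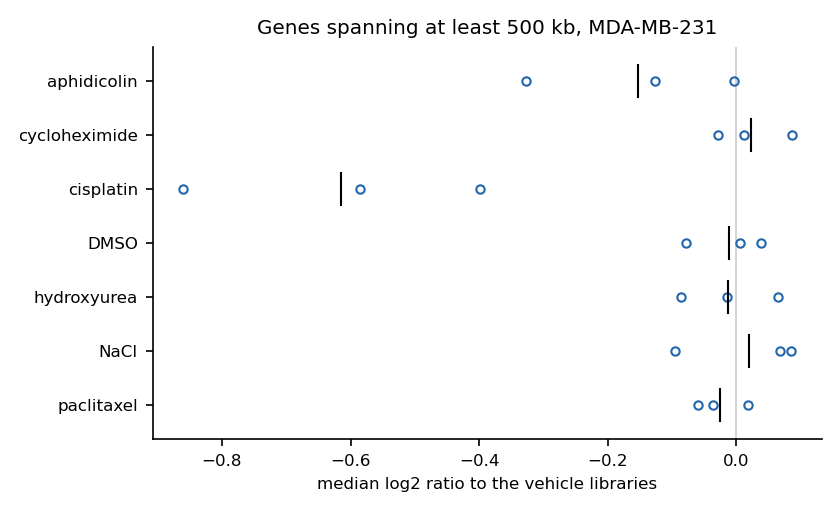
Median log2 ratio to the vehicles of genes spanning at least 500 kb, by library. Open circles are libraries and the black line is the mean of 3. Cisplatin libraries had −0.59, −0.40 and −0.86.

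Interferon-stimulated genes had 14 higher and 0 lower of 38 with cisplatin (16 and 0 adjusted over the list alone, median 0.44, camera adjusted p = 2.11e-07, adjusted p = 0.285 with estimated correlation). NF-kB targets had 2 and 0 of 37 (1 and 0 adjusted over the list alone, median 0.08, camera adjusted p = 0.212). G2/M genes such as KIF20A (−1.03) and PLK1 (−0.87) had 0 and 10 of 40 (1 and 23 adjusted over the list alone, camera adjusted p = 2.11e-07, adjusted p = 0.369 with estimated correlation). DNA replication genes such as DSCC1 (0.63) had 7 and 2 of 56 (13 and 2 adjusted over the list alone, camera adjusted p = 2.01e-04, adjusted p = 0.362 with estimated correlation). Ribosomal proteins had a median of 0.36 with 0 and 0 of 38 (0 and 0 adjusted over the list alone, camera adjusted p = 1.36e-04, adjusted p = 0.630 with estimated correlation), turned in direction without cisplatin 3 (0.598). Without cisplatin 3, E2F (4.11e-06), nucleic acid sensing (3.32e-04), NRF2 (0.00260), cholesterol synthesis (0.00428), histone (0.00439), oestrogen receptor (0.0110) and p53 (0.0129) lists gained a call (camera adjusted p).

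ATF4 targets with cisplatin had 0 and 7 of 29 (0 and 9 adjusted over the list alone, camera adjusted p = 0.00369, adjusted p = 0.362 with estimated correlation), lost without cisplatin 1 (0.0783) or 2 (0.0789). Fanconi anaemia genes had 4 and 1 of 36 (4 and 1 adjusted over the list alone, camera adjusted p = 0.0385, adjusted p = 0.630 with estimated correlation), lost without cisplatin 1 (0.278) or 2 (0.320). The unfolded protein response, with HSPA5 at −0.53, had 0 and 3 of 20 (0 and 5 adjusted over the list alone, camera adjusted p = 0.0385, adjusted p = 0.362 with estimated correlation), lost without cisplatin 1 (0.15), cisplatin 2 (0.120), DMSO 1 (0.0612) or DMSO 2 (0.0501). Mesenchymal markers, with AXL at −0.68, had 1 and 4 of 19 (1 and 4 adjusted over the list alone, camera adjusted p = 0.0443, adjusted p = 0.369 with estimated correlation), lost without cisplatin 1 (0.119), cisplatin 2 (0.0883), DMSO 2 (0.0681) or NaCl 2 (0.0565).

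In total 567 genes rose and 828 fell of 15756 with cisplatin by limma, 91 and 150 by at least 2-fold. The count was 3135 without cisplatin 2, 790 without cisplatin 3, 94 without the libraries numbered 1 and 302 when fitted alone (339 higher and 519 lower with no further scaling, which shifts the median of all genes by −0.10).

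Cycloheximide raised immediate-early genes and lowered cholesterol synthesis genes. The cytokine IL24 rose 11.2-fold (limma adjusted p = 5.03e-05), the immediate-early factor EGR1 8.63-fold (0.00128), IL11 8.24-fold and IL6 6.12-fold to 50.8 ± 18.6 TPM (2.18e-05). The carbonic anhydrase gene CA12 fell to 2.27 ± 0.179 TPM from 46.3 ± 6.16 and 52.0 ± 8.77 TPM (log2 fold change −3.83, limma adjusted p = 3.24e-11). NFKBIA fell (−0.87, limma adjusted p = 0.00144) and ISG15 rose (1.54, 0.00140). All 39 named genes that passed had no overlap, in part by the naming rule.

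Immediate-early genes such as KLF10 (1.75) rose in 23 of 29 members with cycloheximide and fell in 0 (24 and 0 adjusted over the list alone, camera adjusted p = 1.87e-10, adjusted p = 0.484 with estimated correlation). The cholesterol synthesis list, with its member PCSK9 at −2.40, had 0 and 19 of 25 (0 and 19 adjusted over the list alone, camera adjusted p = 2.43e-09, adjusted p = 0.484 with estimated correlation). Ribosome biogenesis genes such as RRP12 (1.59) had 23 and 0 of 34 (26 and 1 adjusted over the list alone, camera adjusted p = 2.20e-10, adjusted p = 0.513 with estimated correlation). Histones such as H2BC12 (1.91) had 9 and 0 of 18 (10 and 0 adjusted over the list alone, camera adjusted p = 2.75e-06, adjusted p = 0.513 with estimated correlation). Ribosomal proteins such as RPL3 (1.04) had 4 and 0 of 38 (2 and 0 adjusted over the list alone, camera adjusted p = 9.82e-05, adjusted p = 0.537 with estimated correlation). ATF4 targets had 5 and 15 of 29 (5 and 17 adjusted over the list alone, camera adjusted p = 0.00252, adjusted p = 0.513 with estimated correlation). NF-kB targets had 11 and 7 of 38 (12 and 8 adjusted over the list alone, limma camera adjusted p = 0.179, called without cycloheximide 3 with 0.0477) and interferon-stimulated genes 9 and 11 of 38 (10 and 11 adjusted over the list alone, camera adjusted p = 0.858).

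In total 2302 genes rose and 2915 fell of 15458 with cycloheximide by limma, 372 and 792 by at least 2-fold (1194 and 3338 with no further scaling, which shifts the median of all genes by −0.14). The count was 7907 without cisplatin 3 and aphidicolin 2 and 2615 without the libraries numbered 1.

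Paclitaxel raised CCL20, IL1A and CXCL1. CCL20 rose to 12.7 ± 4.81 TPM from 0.161 (DMSO) and 0.188 TPM (NaCl), a log2 fold change of 3.47 (limma adjusted p = 2.59e-06), IL1A 7.20-fold (2.59e-06), CXCL1 to 54.3 ± 11.5 TPM (2.33 log2 units, 8.62e-04) and IL1B by 2.11. CXCL8 rose 6.19-fold (limma adjusted p = 0.00412, with 0.0514 without paclitaxel 1). ISG15 had a log2 fold change of 0.10 (limma adjusted p = 0.998) and CDKN1A of 0.45 (0.166). All 30 named genes that passed had no overlap, in part by the naming rule. In total 132 genes rose and 22 fell of 15873 by limma, 56 and 0 by at least 2-fold. The count was 96 without NaCl 1, 51 without paclitaxel 1, 40 without paclitaxel 2, 56 without paclitaxel 3, 228 with a replicate block, 691 when fitted alone, 686 without cisplatin 3 and aphidicolin 2, and 9 without the libraries numbered 1.

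NF-kB targets rose in 13 of 40 members with paclitaxel and fell in 0 (22 and 0 adjusted over the list alone, median 0.55, camera adjusted p = 1.93e-34, adjusted p = 0.111 with estimated correlation). Immediate-early genes such as NR4A3 (1.39) rose in 7 of 30 and fell in 0 (17 and 0 adjusted over the list alone, camera adjusted p = 1.89e-21), which held with adjusted p = 0.0138 with estimated correlation. The secretome had 6 and 0 of 22 (13 and 0 adjusted over the list alone, camera adjusted p = 7.20e-17, adjusted p = 0.0851 with estimated correlation). NRF2 targets had 1 and 0 of 24 (6 and 0 adjusted over the list alone, camera adjusted p = 2.30e-07, adjusted p = 0.257 with estimated correlation). Histones had 3 and 0 of 16 (9 and 0 adjusted over the list alone, camera adjusted p = 2.44e-07, adjusted p = 0.111 with estimated correlation). G2/M genes had 0 and 3 of 40 (0 and 11 adjusted over the list alone, camera adjusted p = 1.08e-21, adjusted p = 0.111 with estimated correlation). ATF4 targets had 0 and 3 of 29 (1 and 5 adjusted over the list alone, camera adjusted p = 0.00960, adjusted p = 0.418 with estimated correlation).

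Interferon-stimulated genes with paclitaxel had 0 and 0 of 39 (0 and 0 adjusted over the list alone, median 0.11, less than between vehicles, camera adjusted p = 0.0267, adjusted p = 0.298 with estimated correlation), lost without DMSO 3 (0.0680), NaCl 3 (0.0507) or paclitaxel 1 (0.0628). The p53 targets had 1 and 0 of 34 (1 and 0 adjusted over the list alone, camera adjusted p = 0.0267, adjusted p = 0.129 with estimated correlation), lost without DMSO 3 (0.0554). DNA replication, Fanconi anaemia and apoptosis lists were called with 0 members past the test (0 adjusted over the list alone, camera adjusted p = 3.93e-05, 8.30e-06 and 0.0264, adjusted p = 0.418, 0.111 and 0.111 with estimated correlation). Tubulins had 1 and 0 of 12 (2 and 1 adjusted over the list alone, limma camera adjusted p = 0.332).

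Set against aphidicolin, hydroxyurea and cisplatin, the POLE change in MDA-MB-231 was larger for the NF-kB list. It exceeded aphidicolin by a median of 1.11 log2 units (3 larger and 0 smaller of 38, 25 and 0 adjusted over the list alone, camera adjusted p = 1.04e-20, held with adjusted p = 0.0222 with estimated correlation), hydroxyurea by 1.01 (2 and 0, 18 and 0 adjusted over the list alone, camera adjusted p = 1.26e-20, adjusted p = 0.0349 with estimated correlation) and cisplatin by 1.25 (19 and 0 of 37, 31 and 0 adjusted over the list alone, camera adjusted p = 1.71e-21, adjusted p = 0.0103 with estimated correlation). The list also exceeded cycloheximide by 1.43 (21 and 0, 21 and 0 adjusted over the list alone, camera adjusted p = 9.27e-10, adjusted p = 0.104 with estimated correlation) and paclitaxel by 0.74 (2 and 0 of 40, 11 and 0 adjusted over the list alone, camera adjusted p = 6.00e-14, adjusted p = 0.0720 with estimated correlation), calls lost in the smaller fit with that correlation.

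Interferon-stimulated genes after POLE knockdown differed by 0.15 from aphidicolin (limma camera adjusted p = 0.0903) and by 0.16 from hydroxyurea (0.0737), without a call. Both were called without POLE control 1 (0.0440 and 0.0368) or knockdown 1 (0.0328 and 0.0256), the former also without aphidicolin 1 (0.0125) and the latter without cisplatin 3 (0.0464) or DMSO 3 (0.0395). The list exceeded cisplatin by 0.41 (4 and 0, 13 and 0 adjusted over the list alone, camera adjusted p = 2.46e-06, held with adjusted p = 0.0175 with estimated correlation), cycloheximide by 0.82 (21 and 0, 26 and 1 adjusted over the list alone, camera adjusted p = 1.65e-08, held with adjusted p = 0.00315 with estimated correlation) and paclitaxel by 0.85 (10 and 0, 21 and 0 adjusted over the list alone, camera adjusted p = 1.77e-25, held with adjusted p = 3.08e-04 with estimated correlation). POLE and compound libraries have separate controls and different durations, so duration and vector are part of these differences.

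Genes that rose after POLE knockdown in MDA-MB-231 shared 614 members with those that rose with hydroxyurea, against 169 from chance (adjusted Fisher p = 8.74e-225 across genes), and 350 fallen genes against 64.2 (2.04e-180), with a Pearson correlation of 0.62 across genes. Aphidicolin shared 544 against 154 (5.28e-187) and 249 against 57.6 (8.82e-97), with a correlation of 0.51. Paclitaxel shared 54 against 10.2 (3.64e-26) and 7 against 1.15 (1.41e-04), with 0.43, and cisplatin 165 against 45.1 (8.05e-52) and 137 against 43.3 (1.07e-34), with 0.22. Cycloheximide shared 257 against 183 (5.74e-09) and 188 against 154 (0.00271), with 0.08, and POLD1 knockdown had a correlation of −0.03. Genes are not independent replicates, and 171, 185, 580, 3788 and 107 genes differed from aphidicolin, hydroxyurea, cisplatin, cycloheximide and paclitaxel in turn.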

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

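The swap, POLE level and 500 kb gene tests below were chosen after the results were seen. The values that follow were singled out by tests of the POLE effect between lines or against POLD1, with 3 libraries per group. Counts of genes past limma were 155 for MDA-MB-231 minus MCF7, 46 for Hs578T minus MCF7, 110 for MDA-MB-231 minus Hs578T and 472 for POLE minus POLD1.

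Interferon-stimulated genes had median log2 differences of 0.65 (MDA-MB-231 minus MCF7), 0.87 (MDA-MB-231 minus Hs578T) and 0.68 (POLE minus POLD1). NF-kB targets had 1.04 (MDA-MB-231 minus MCF7), 0.41 (Hs578T minus MCF7), 0.57 (MDA-MB-231 minus Hs578T) and 1.13 (POLE minus POLD1). The secretome had 0.14 (MDA-MB-231 minus MCF7, camera adjusted p = 0.0434, adjusted p = 0.305 with estimated correlation) and 0.59 (POLE minus POLD1, 0.00108 and 0.0976). The former was lost without MDA-MB-231 control 2 (0.278) or knockdown 1 (0.168), or MCF7 control 1 (0.106), control 2 (0.0748), knockdown 1 (0.0541) or knockdown 2 (0.0522). The p53 targets had −0.20 (MDA-MB-231 minus MCF7), −0.24 (Hs578T minus MCF7) and 0.20 (POLE minus POLD1).

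DNA replication genes had 0.10 (Hs578T minus MCF7, camera adjusted p = 0.00469, 0.0506 without Hs578T control 3), −0.20 (MDA-MB-231 minus Hs578T, 4.94e-06) and −0.33 (POLE minus POLD1, 4.46e-10). G2/M genes had 0.14 (Hs578T minus MCF7, camera adjusted p = 0.0102), −0.25 (MDA-MB-231 minus Hs578T, 2.19e-05) and −0.51 (POLE minus POLD1, 1.28e-08), with adjusted p = 0.235 to 0.596 with estimated correlation for these 6. The G2/M call of Hs578T minus MCF7 was lost without Hs578T control 1 (0.445), control 2 (0.883) or knockdown 2 (0.144) or 3 (0.0570) or MCF7 control 3 (0.307), and that of MDA-MB-231 minus Hs578T without MDA-MB-231 knockdown 1 (0.0597) or Hs578T control 2 (0.0702).

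Single genes of MDA-MB-231 minus MCF7 were the cytokine mRNA nuclease ZC3H12A (2.43), MALL (−1.62) and the vitamin D hydroxylase CYP24A1 (−1.65), with limma adjusted p = 0.0268 for ZC3H12A and 0.0784 without MDA-MB-231 control 2. For Hs578T minus MCF7 they were PPP1R14C (1.82), OLFM1 (1.65) and LAMP3 (−1.96). The call of PPP1R14C was lost without Hs578T control 1 (limma adjusted p = 0.117) and that of OLFM1 without MCF7 control 2 (0.0799). For MDA-MB-231 minus Hs578T they were LAMP3 (2.92), ICAM2 (1.80), CXCR4 (−3.99) and ESM1 (−7.43), and for POLE minus POLD1 TNFSF15 (2.61), the interferon chemokine CXCL11 (2.54), CCDC61 (−1.35) and MCIDAS (−1.38). The last 3 were lost without POLE knockdown 3 (limma adjusted p = 0.0997), POLD1 control 2 (0.0972) and POLD1 control 1 (0.115). These 3, ZC3H12A, PPP1R14C and OLFM1 each lost the call with 7 to 10 libraries left out in turn.

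Libraries were relabelled to ask about chance. Of 100 splits, 6 (MDA-MB-231 minus MCF7), 7 (Hs578T minus MCF7), 8 (MDA-MB-231 minus Hs578T) and 12 (POLE minus POLD1) gave as many genes as the real one, itself included, with 645, 493, 1081 and 1935 genes in the highest other split. Of the others, 5 of 5, 5 of 6, 6 of 7 and 4 of 11 kept the groups of 1 arm intact, and with them its knockdown effect. With neither arm intact 0 of 77, 1 of 83, 1 of 79 and 7 of 80 reached the count (highest 0, 57, 115 and 1935 genes), but these mix real groups, so whether chance gave the 4 counts could not be told. The 10 splits of 3 against 3 libraries are too few for a share under 0.05. There 1 of 10 reached the real count for POLE in MDA-MB-231 (2164, highest other 0), Hs578T (723, highest other 699, knockdown 1 with controls 1 and 2) and MCF7 (152, highest other 0), and 2 of 10 for POLD1, where the highest other, knockdown 1 with controls 1 and 2, called 3949 against 1. Such splits point to structure among the samples. For NaCl minus DMSO 10 of 10 splits reached the count of 0. For the compounds 1 of 84 splits reached the real count, with highest others of 330 (aphidicolin), 548 (hydroxyurea), 62 (cisplatin), 1066 (cycloheximide) and 5 genes (paclitaxel). This speaks against chance among libraries, but not cultures if replicates are technical. Replicate numbers pair some libraries. Of the 27 splits with each number once among the treated, 1 reached each real count, with the same highest others.

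The POLD1 arm varied across its labels more than between its groups. A swap of libraries is argued against by POLD1 itself, since the lowest control divided by the highest knockdown level was 22.3. RNA quality acting through transcript length is argued against by a Spearman correlation across genes of −0.0777 with the loadings of the first component. A culture state shared with the POLE controls of MDA-MB-231 could not be told (absolute correlation across genes 0.230), and it may be that density or infection differed between libraries, which was not recorded.

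NF-kB targets had a lower median change in MCF7 than in MDA-MB-231. Low level in MCF7 is argued against as the sole cause, since 8 members with at least 10 TPM in MCF7 had a median difference of 1.04 and group medians of 1.10 in MDA-MB-231 and 0.05 in MCF7. A less complete loss of POLE could not be told, since MCF7 and MDA-MB-231 knockdown levels had a ratio of 1.03 and untouched MCF7 was not measured. Control POLE differed too (174 and 629 TPM), with untested effect. A difference between the lines in NF-kB signalling remains possible.

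Long genes were lower after cisplatin. A general effect of blocked replication is argued against by hydroxyurea (Spearman correlation of 0.0610 with span across genes), while aphidicolin had −0.177 (−0.0420 given transcript length), with −0.366 in aphidicolin 2 and −0.00334 and 0.0601 in the others. RNA quality acting through transcript length remains open, since the weaker partial correlation given transcript length, in cisplatin 2, was −0.0158, and whether 1 library decides the trend could not be told (weaker correlation −0.0563). For genes of at least 500 kb the weakest of the 3 libraries still had a median of −0.354 against shorter genes of the same transcript length, which argues against that explanation for them.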

How the results depend on the processing

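Counts of changed genes follow. With a 2-fold threshold they were 348 (POLE in MDA-MB-231), 170 (Hs578T), 31 (MCF7), 76 (MDA-MB-231 minus MCF7), 24 (Hs578T minus MCF7), 61 (MDA-MB-231 minus Hs578T), 181 (POLE minus POLD1), 574 (aphidicolin), 722 (hydroxyurea), 241 (cisplatin), 1164 (cycloheximide) and 56 (paclitaxel), fewer by construction. No further scaling gave 69 (MDA-MB-231 minus Hs578T) and 858 (cisplatin), pseudocount 0.1 gave 2 (POLD1), and no filter gave 110 (Hs578T minus MCF7), 302 (POLE minus POLD1) and 5 (NaCl minus DMSO). A stricter filter (mean CPM of at least 5) gave 29 (Hs578T minus MCF7), 69 (MDA-MB-231 minus Hs578T), 2113 (hydroxyurea) and 73 (paclitaxel), with fewer genes tested. Only the libraries of the comparison gave 81 (Hs578T), 473 (MDA-MB-231 minus MCF7), 11 (Hs578T minus MCF7), 20 (MDA-MB-231 minus Hs578T), 240 (POLE minus POLD1), 5289 (hydroxyurea), 302 (cisplatin) and 691 (paclitaxel). A replicate block gave 21 (Hs578T minus MCF7), 748 (POLE minus POLD1) and 1 (NaCl minus DMSO). DMSO alone gave 818 (cisplatin) and 74 (paclitaxel), and NaCl alone 2029 (aphidicolin), 715 (cisplatin) and 79 (paclitaxel), with fewer samples. The other causes were not tested.

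Alternatives chosen after seeing the data also moved counts. Limma-voom gave 98 (MDA-MB-231 minus MCF7) and 15 (Hs578T minus MCF7). Array quality weights gave 4586 (POLE in MDA-MB-231), 1920 (Hs578T), 877 (MCF7), 7121 (POLD1), 1460 (MDA-MB-231 minus MCF7), 474 (Hs578T minus MCF7), 879 (MDA-MB-231 minus Hs578T), 6665 (POLE minus POLD1), 4814 (aphidicolin), 6012 (hydroxyurea), 530 (cisplatin), 8921 (cycloheximide), 1929 (paclitaxel) and 9 (NaCl minus DMSO). Without cisplatin 3 and aphidicolin 2 the counts were 4579 (aphidicolin), 5964 (hydroxyurea), 7907 (cycloheximide) and 686 (paclitaxel), and without the libraries numbered 1 they were 815, 1058, 94 (cisplatin), 2615 and 9, with fewer samples. Leaving out POLD1 knockdown 1 and control 3 gave 1857 (POLD1) and 3519 (POLE minus POLD1). It was withdrawn for keeping only libraries that part by group. Estimated correlation, in fits of the libraries of the comparison alone, kept 3 of 95 list calls and 6 of 18 called differences, and fry called 10 differences. The cause was not tested for weights and for limma-voom.

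With each library left out in turn the counts ranged from 1194 to 1928 (POLE in MDA-MB-231), 365 to 1039 (Hs578T), 23 to 102 (MCF7), 1 to 5 (POLD1), 70 to 230 (MDA-MB-231 minus MCF7), 8 to 90 (Hs578T minus MCF7), 36 to 192 (MDA-MB-231 minus Hs578T) and 153 to 1666 (POLE minus POLD1). For the compounds they ranged from 2324 to 2784 (aphidicolin), 2110 to 3060 (hydroxyurea), 790 to 3135 (cisplatin), 3839 to 4914 (cycloheximide), 40 to 132 (paclitaxel) and 0 to 0 (NaCl minus DMSO). List calls ranged from 90 to 101, called differences from 16 to 20, differences from compounds from 8 to 10, overlaps past the test from 13 to 14, and target genes from 4 to 4. Of 263 list results 190, and of 495 named gene results 351, kept their call and direction with every single library left out.

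Results that turned direction were few. The G2/M list in Hs578T turned with array quality weights (camera adjusted p = 0.591) and without control 3 (0.0554), with a range of 4.89e-07 to 0.470 over libraries left out. The ribosomal protein list in MCF7 turned without MCF7 control 3 (0.0249), with a range of 0.0249 to 0.973 (camera adjusted p). With cisplatin, ribosomal proteins turned without cisplatin 3 (camera adjusted p = 0.598, the highest of a range from 6.56e-07) and without cisplatin 3 and aphidicolin 2 (0.404). CCNE2 with cisplatin had a log2 fold change of −0.02, of 0.77 with array quality weights, of 0.85 without that pair and of −0.48 to 0.87 with each library left out, the highest without cisplatin 3. The cause was not tested. Of 263 list and 495 named gene results, call and direction held for 263 and 494 with median-of-ratios scaling, 251 and 460 with no further scaling, 259 and 467 with pseudocount 0.1, 238 and 440 with no filter, 259 and 471 with a replicate block, 261 and 445 with limma-voom, 231 and 449 with array quality weights, and 250 and 411 with only the libraries of the comparison. For fewer results they held for 236 of 254 and 381 of 389 with the stricter filter, 111 of 119 and 217 of 245 with DMSO alone, 112 of 119 and 203 of 245 with NaCl alone, 128 of 144 and 241 of 257 without cisplatin 3 and aphidicolin 2, and 131 of 144 and 162 of 251 without the libraries numbered 1. The planned DESeq2 test was not run, since the values are TPM.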
